A study of Homo sapiens with 12 samples.

How the data were processed

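RNA of Caco-2 cells, transfected with GPX4 or scrambled siRNA at 60 or 120 pmol, was measured on 12 Illumina HumanHT-12 V3 arrays, 3 per combination of siRNA and dose. Per the labels' protocols, RNA was extracted with Trizol, cleaned, treated with DNase I, amplified and labelled with biotin. Signals are intensities of the mean bead signal per probe, deposited without normalization or background subtraction by GenomeStudio 1.1.1, per the file headers. Beside each intensity the deposited table gives a detection score, which is 1 minus a detection p against the negative control probes of the array, the SD over beads and the number of beads. A further deposited table repeats the same signals under ILMN probe IDs, and all 48798 probes of both tables were joined by identical signals on all 12 arrays.

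The authors' series table holds log2 values. Its scale, centring and direction are stated nowhere and were found from the values: each is the log2 signal minus the 75th percentile of its array and minus the median of its probe over the 12 arrays, which gave 100% of the values within 0.01. Higher values mean more signal. The column medians of these log2 values by the authors were −0.018, −0.0242 and −0.0146 for scrambled 60 replicates 1, 2 and 3, and −0.000298, −0.0109 and −0.0021 for GPX4 siRNA 60. They were 0.00447, 0.00359 and 0.0253 for scrambled 120, and 0.0268, 0.0195 and −0.00754 for GPX4 siRNA 120. This table served as an alternative only.

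The deposited signals were background-corrected with limma 3.58.1 in R 4.3.3 (the normexp model with negative controls inferred from the detection p, offset 16), quantile normalized and put on the log2 scale. Probes with a detection p under 0.05 on at least 3 of 12 arrays were kept (18020 of 48798), and each symbol was represented by its probe with the highest mean, which gave 14171 genes, of which 3026 had more than 1 kept probe. Of the probes, 24105 carried a current symbol and 4489 an older symbol of 1 gene, while 20204 matched no gene of the RefSeq table and kept the file's name. No genome coordinates are given, since the files name no build. A gene not above background on any array of a group is given as at least a fold, from the bright group's mean over the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own, or without a size where this holds at a single dose of the mean over both.

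Group means over all 12 arrays were fitted with limma and moderated by eBayes, with p-values adjusted by Benjamini and Hochberg within each comparison and a threshold of 0.05. The comparisons were GPX4 against scrambled siRNA as the mean of both doses, at 60 pmol and at 120 pmol, the difference of these effects between doses, and 120 against 60 pmol within each siRNA. Gene lists fixed before the data were examined, 43 in number, were tested with camera (preset correlation 0.01), and also with an estimated correlation and with fry; 42 had at least 5 measured members. Single GPX4 probes were tested by exact two-sided permutation. The named genes follow a rule fixed beforehand. It takes GPX4, then for the mean of both doses the 12 largest rises and 12 largest falls past the threshold whose treated arrays all lie on one side of the scrambled arrays at both doses. For every other comparison it takes the 5 largest rises and 5 largest falls past the threshold (without overlap for a single dose), and for each list up to 4 members with the smallest p, with every measured selenoprotein.

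The test was tested on simulated data with the real spread of the 14171 genes. In each simulation 200 genes were changed at both doses of GPX4 siRNA and a further 200 at 120 pmol only. Recovery was counted over the former for GPX4 against scrambled siRNA, and over the latter for comparisons between doses. For the mean of both doses the test recovered 40.9, 93.4 and 100% of genes changed by 0.5, 1 and 2 on the log2 scale, with 4.34% false calls. At 60 pmol it recovered 7.16, 62.7 and 99.4% (3.44% false), at 120 pmol 10.4, 74 and 100% (6.01% false), for the difference between doses 0.299, 23.3 and 87.9% (3.66% false) and between GPX4 siRNA doses 7.76, 66.3 and 98.8% (4.01% false). Between the scrambled doses, where nothing was changed, it made 0 calls. Camera called 105 of 105 simulated lists shifted by 0.3 and, as higher, 0 of 80 lists not shifted. The simulated genes varied independently of each other and no simulated array was outlying. The simulation therefore does not show how often camera calls a list wrongly in the real arrays.

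The alternatives tried were no background correction, median scaling, the authors' series values, no filter, a strict filter (detection p under 0.01 on all arrays), every probe on its own, only the arrays of the comparison, the replicate number as a block, a trended robust variance, array weights and leaving out each array in turn. Leaving out 2 arrays together was added after the data were seen. Replicate numbers were not used to pair samples. A block for the slide was not run, since the files name none. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.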

Results

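Gene expression was measured in Caco-2, an established human colorectal carcinoma line used as a model of the intestinal epithelium, after transfection with siRNA against GPX4 or with a scrambled siRNA. GPX4 is the selenoprotein that reduces lipid hydroperoxides within membranes. Each siRNA was given at 60 and at 120 pmol, RNA was taken 72 h later, and every combination was represented by 3 samples, each on its own Illumina HumanHT-12 V3 array, 12 arrays in all. The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value. The median signal of an array lay between 89 and 108.7, and 11779 to 12298 genes per array had a detection p under 0.05. The array labelled scrambled 60 replicate 1 stood apart: its median correlation with the other arrays was 0.964, against 0.980 to 0.987 for the remaining 11 arrays. The lowest of these 11, 0.980, belonged to scrambled 120 replicate 2.

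GPX4 mRNA was lower in the cells given GPX4 siRNA. On the brighter of the gene's 2 probes, ILMN_2378952, the mean of both doses fell by 0.88 ± 0.16 on the log2 scale (SE, 6 arrays against 6), which left 54.5% of the control level (limma adjusted p = 0.00869). The other probe, ILMN_1734353, fell by 1.11 ± 0.18, leaving 46.2% (limma adjusted p over all probes = 0.00483). In exact two-sided permutation tests within doses, p was 0.005 for ILMN_2378952, the smallest that the design allows, and 0.01 for ILMN_1734353. The signal of ILMN_2378952 was 3401, 9331 and 8670 in scrambled replicates 1, 2 and 3 at 60 pmol (7134 ± 3250, SD, n = 3), and 3153, 3962 and 3857 with GPX4 siRNA (3657 ± 440). At 120 pmol it was 6955, 5893 and 6495 with scrambled siRNA (6448 ± 532) and 3466, 2656 and 3643 with GPX4 siRNA (3255 ± 526). ILMN_1734353 gave 1429, 4139 and 3886 with 60 pmol scrambled siRNA (3151 ± 1497), against 1347, 1274 and 1375 with GPX4 siRNA (1332 ± 52.1). Its signals at 120 pmol were 3212, 2621 and 2363 with scrambled siRNA (2732 ± 436) and 1086, 1209 and 1163 with GPX4 siRNA (1153 ± 61.8). The array labelled scrambled 60 replicate 1 thus had a GPX4 signal close to that of the GPX4 siRNA arrays, and every direction at 60 pmol draws on it.

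Taken dose by dose, GPX4 did not pass the threshold over all 12 arrays. Its log2 fold change was −0.82 ± 0.22 at 60 pmol (limma adjusted p = 0.148) and −0.93 ± 0.22 at 120 pmol (limma adjusted p = 0.111) on ILMN_2378952. With 3 arrays against 3, the exact permutation p was 0.1 at each dose on this probe, the smallest possible. On ILMN_1734353 it was 0.2 at 60 pmol and 0.1 at 120 pmol. Without the array labelled scrambled 60 replicate 1, both doses passed on both probes. ILMN_2378952 was at −1.14 (limma adjusted p over all probes = 0.0111) and −0.94 (0.0108), against such p of 0.171 and 0.121 over all 12 arrays. ILMN_1734353 was at −1.42 (0.00205) and −1.24 (0.00196), against 0.151 and 0.0641. That array had the lowest GPX4 signal of the scrambled 60 arrays, so leaving it out was bound to enlarge the fall at 60 pmol. The exact permutation p at 60 pmol was then 0.1 on both probes, the smallest possible. The GPX4 effect did not differ detectably between doses, with a difference of −0.11 ± 0.31 (limma adjusted p = 0.964).

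**Figure D1:**
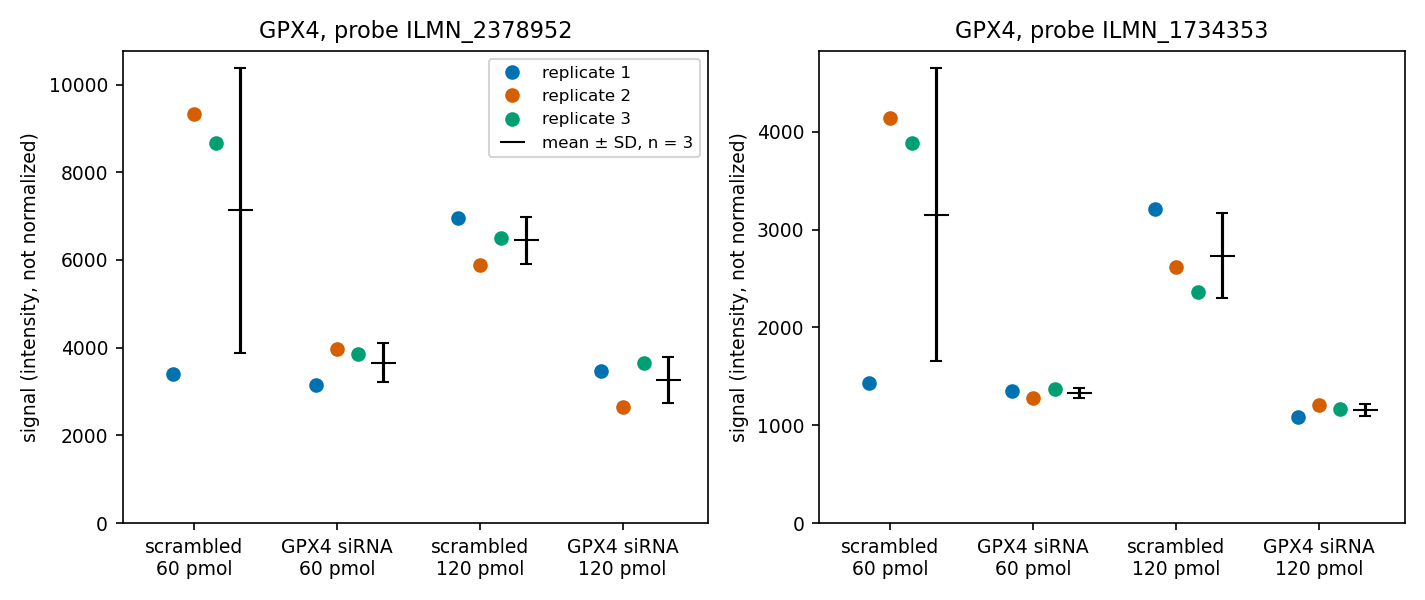
GPX4 signal (intensity, not normalized) on each array for both GPX4 probes, by group, with points coloured by replicate and bars at the mean ± SD of 3 arrays. For ILMN_2378952 the GPX4 siRNA arrays lie between 2656 and 3962, and the array labelled scrambled 60 replicate 1, at 3401, lies among them.

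Across both doses, GPX4 siRNA was compared with scrambled siRNA to ask which transcripts differ between cells given these siRNAs. The siRNA sequences are not given, so off-target effects were not tested, and each fold change is that of the GPX4 siRNA, whether through GPX4 or not. PAGE4, a member of a cancer/testis-associated gene family, rose by 2.11 ± 0.18 (log2 fold change ± SE), and NKD1, an antagonist and target of Wnt signalling, by 1.63 ± 0.10. COL3A1, a chain of type III collagen, rose by 1.53 ± 0.13 and MYBPH, a myosin-binding protein, by 1.51 ± 0.13. IGFBP1, which binds insulin-like growth factors, was not above background on any scrambled array and was at least 3.61-fold higher with GPX4 siRNA on its brightest probe. Its other probe had a log2 fold change of 0.99. The limma adjusted p was 8.34e-06 for PAGE4, COL3A1 and MYBPH, 5.44e-07 for NKD1 and 8.95e-07 for IGFBP1. RN7SK, the small nuclear RNA that restrains the elongation factor P-TEFb, rose by 1.37 ± 0.17, and the insulin-like growth factor family member IGFL2 by 1.25 ± 0.22. Another selenoprotein, the cytosolic glutathione peroxidase GPX1, rose by 1.18 ± 0.16 (limma adjusted p = 0.000798). The stress-inducible transcription factors ATF3 and JUN rose by 1.17 ± 0.12 and 1.15 ± 0.12, and ID3, an inhibitor of helix-loop-helix transcription factors, by 1.07 ± 0.15. HS.187578, a transcript cluster without a gene name in the file, rose by 1.46 ± 0.14.

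Among called genes whose treated and scrambled arrays did not overlap at either dose, the largest fall was that of EVL. This actin regulator of the Ena/VASP family was at −1.80 ± 0.13 (limma adjusted p = 8.95e-07). All 3 fibrinogen chain genes fell, FGA by 1.31 ± 0.15, FGB by 1.22 ± 0.14 and FGG by 1.06 ± 0.14. The 3 further FGA probes had log2 fold changes of −1.44, −0.46 and −1.40. SLC10A1, the sodium-dependent bile acid importer of hepatocytes, fell by 1.34 ± 0.16, but was detected on only 1 of 3 GPX4 siRNA arrays at each dose. STOM, the membrane protein stomatin, fell by 1.33 ± 0.14, the heparan sulfate proteoglycan gene GPC5 by 1.17 ± 0.15 and the calpain protease gene CAPN5 by 1.01 ± 0.13. RAB31, a small GTPase of vesicle transport, fell by 0.97 ± 0.12, FAM151A by 0.97 ± 0.18, and HOGA1, a mitochondrial aldolase gene listed as C10ORF65, by 0.95 ± 0.11. SLC23A1, a vitamin C transporter, had a log2 fold change of −1.17 ± 0.15 (limma adjusted p = 0.000582) on its brightest probe, which was detected on 2 of 3 GPX4 siRNA arrays at each dose, and −0.09 on its other probe. The call of SLC23A1 was lost without scrambled 60 replicate 1, any of the 3 scrambled 120 arrays, or GPX4 siRNA 120 replicate 2, with adjusted p up to 0.990, since the other probe then counted as the brightest. The other 23 of these 24 genes passed in all 12 fits that left out 1 array. Their choice as large calls without overlap on these same arrays favours this. Of all 282 calls, 144 to 168 were kept in the same direction on leaving out 1 GPX4 siRNA array.

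In total 282 of 14171 genes changed, 90 up and 192 down (limma adjusted p under 0.05), and 2437 genes had an unadjusted p under 0.05 where chance gives 709. With the values of the authors' series table the split was 90 up and 420 down. Leaving out 1 array gave 147 to 504 genes: 159, 151 and 147 without GPX4 siRNA 60 replicates 1, 2 and 3, 159, 181 and 155 without GPX4 siRNA 120 replicates 1, 2 and 3, 184 without scrambled 120 replicate 3, and 504 without scrambled 60 replicate 3.

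**Figure D2:**
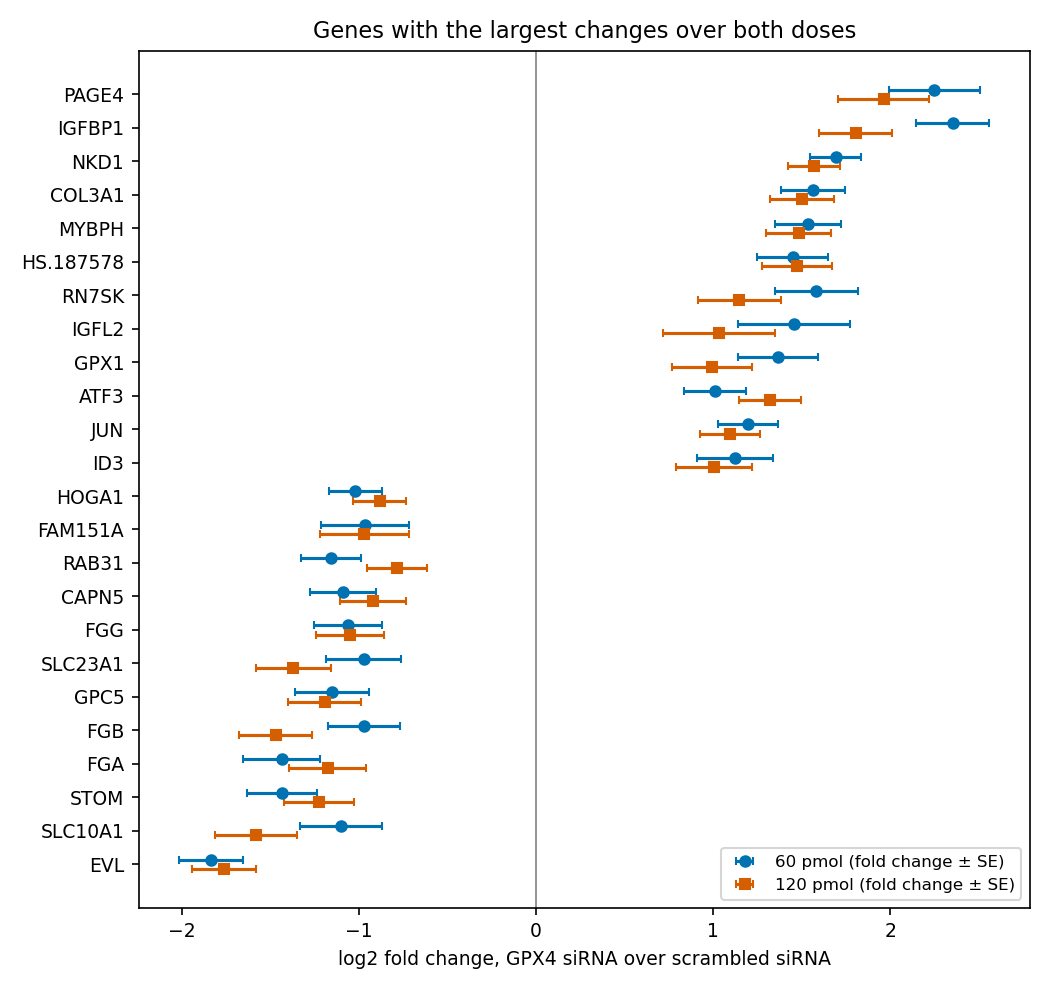
Log2 fold change of GPX4 siRNA over scrambled siRNA at 60 pmol (circles) and 120 pmol (squares), with bars of 1 SE. Shown are the 12 largest rises and 12 largest falls over both doses among called genes whose treated and scrambled arrays did not overlap at either dose. Genes are ordered by the mean of both doses, from PAGE4 (2.25 and 1.96) to EVL (−1.84 and −1.76). The choice of genes fixes that both doses have the same sign. The point of IGFBP1 is the fitted value, with scrambled arrays below background.

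Genes known as Wnt targets or markers of intestinal progenitors were higher as a group. Of 22 measured, 8 rose, 1 fell and 13 did not pass (12 up and 2 down when adjusted over the list alone). Besides NKD1, LEF1, a transcription factor that acts with beta-catenin, rose by 1.03 ± 0.11 (limma adjusted p = 9.34e-05). SP5, a transcription factor induced by Wnt, rose by 0.82 ± 0.12 (0.00149), and AXIN2, a feedback inhibitor of the pathway, by 0.70 ± 0.11 (0.00398). The median over the list was 0.38, and camera gave an adjusted p of 5.89e-08 with the preset correlation and 0.0117 with an estimated correlation. This was the only one of 42 tested lists whose call held with an estimated correlation, and with the preset correlation it passed under each of the 22 other processing settings tried. Enterocyte brush border genes were lower as a group by the preset-correlation test (median −0.17, camera adjusted p = 0.0117), but not with an estimated correlation (adjusted p = 0.181). MYO1A, a brush border myosin, fell by 0.55 ± 0.14 (limma adjusted p = 0.0498, passing in only 2 of the 12 fits with 1 array left out, adjusted p up to 0.119). No member rose and 17 of 18 did not pass (0 up and 3 down when adjusted over the list alone). Values for the microvillus proteins VIL1 and USH1C were −0.37 and −0.46, and for intestinal alkaline phosphatase, ALPI, −0.34. The preset-correlation call passed under all 22 other settings.

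**Figure D3:**
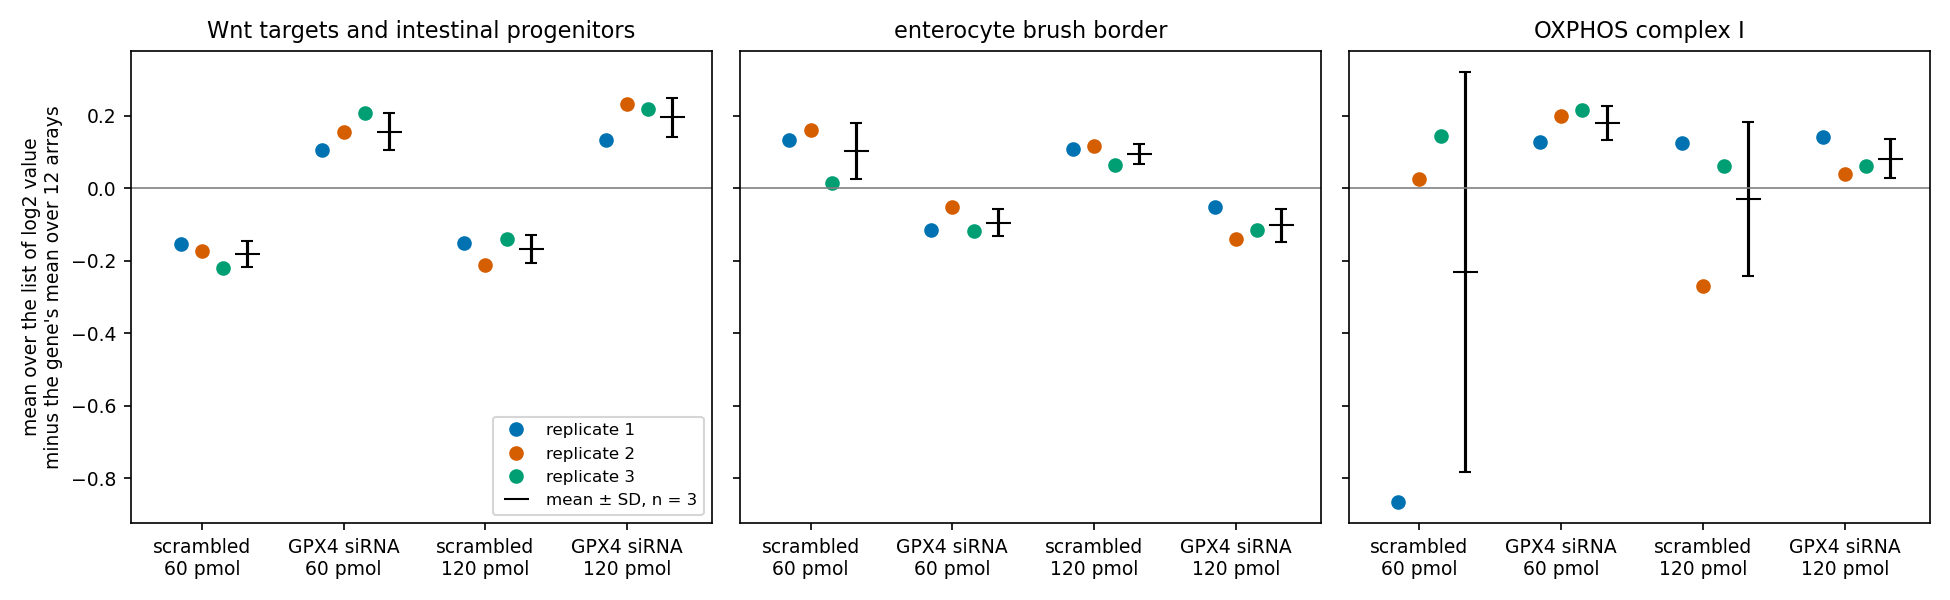
Mean deviation from each gene's average over 12 arrays (log2) for the Wnt, brush border and complex I lists on each array, by group, with bars at the mean ± SD of 3 arrays. The Wnt list lies between −0.22 and −0.14 on scrambled and between 0.10 and 0.23 on GPX4 siRNA arrays, while for complex I the array labelled scrambled 60 replicate 1 lies at −0.86 and scrambled 120 replicate 2 at −0.27.

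Nuclear genes of the mitochondrial respiratory chain and ribosome were higher as groups by the preset-correlation test, with few members passing singly, and none of these calls held with an estimated correlation (adjusted p from 0.462 to 0.632). For complex IV, which passes electrons to oxygen, 0 of 11 genes passed (0 when adjusted over the list alone). Its median was 0.41 (camera adjusted p = 0.000253, and adjusted p = 0.515 with an estimated correlation), with COX8A at 0.62, COX6A1 at 0.51, NDUFA4 at 0.41 and COX5A at 0.35. For complex I, the NADH dehydrogenase, 0 of 31 passed (0 over the list alone), with NDUFB6 at 0.84 and NDUFC1 at 0.64. The median was 0.24 (adjusted p = 0.00187, and adjusted p = 0.632 with an estimated correlation). For complex V, the ATP synthase, 0 of 14 rose and 1 fell (5 up and 1 down when adjusted over the list alone), with ATP5ME at 0.83 and a median of 0.41 (adjusted p = 0.0171, and adjusted p = 0.462 with an estimated correlation). The member that fell was ATP5F1C, the gamma subunit, by 0.45 ± 0.11 (limma adjusted p = 0.0353, passing in 2 of the 12 fits with 1 array left out, adjusted p up to 0.0955). Of 72 mitochondrial ribosome genes 0 rose and 1 fell (1 up and 2 down when adjusted over the list alone), with a median of 0.18 (adjusted p = 0.000106, and adjusted p = 0.542 with an estimated correlation). That gene, MRPL10, fell by 0.53 ± 0.12 (limma adjusted p = 0.0316, passing in 4 of the 12 such fits, adjusted p up to 0.0847). On the array labelled scrambled 60 replicate 1 the complex I genes lay 0.86 below their average, and on scrambled 120 replicate 2 they lay 0.27 below. Without the array labelled scrambled 60 replicate 1, complex I (adjusted p = 0.15) and complex V (0.0959) lost their calls, while complex IV and the mitochondrial ribosome (both 0.0214) did not. With array weights complexes I and V and the mitochondrial ribosome lost theirs. Without both arrays none of the 4 lists passed, with adjusted p from 0.165 to 0.428. Mitochondrial import (median 0.11, adjusted p = 0.0511, but 0.04 with no background correction and 0.044 with median scaling), complexes II and III (0.14, 0.147), the tricarboxylic acid cycle (−0.06, 0.581) and coenzyme Q synthesis (−0.12, 0.289) did not pass, and none of their genes did; over the list alone import had 2 up and 1 down and the others 0.

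Lipid genes fell in part. DGAT1, the enzyme of the last step of triglyceride synthesis, fell by 0.72 ± 0.11 (limma adjusted p = 0.00238), as did APOA1, the main apolipoprotein of high-density lipoprotein, by 0.78 ± 0.12 (0.00279). Both passed in all 12 fits with 1 array left out. The acylcarnitine carrier gene SLC25A20 fell by 0.63 ± 0.14 (0.0261, passing in 5 of the 12 such fits, adjusted p up to 0.0816). Of 21 measured fatty acid oxidation genes 0 rose, 2 fell and 19 did not pass (0 up and 2 down when adjusted over the list alone). The median of that list was −0.20 (camera adjusted p = 0.0208, and adjusted p = 0.44 with an estimated correlation). For fatty acid and triglyceride synthesis, DGAT1 alone of 19 passed (0 up and 2 down over the list alone), with a median of −0.15 (adjusted p = 0.0406, and adjusted p = 0.462 with an estimated correlation). Both lists lost their calls without the array labelled scrambled 60 replicate 1 or scrambled 120 replicate 2, and the synthesis list also without GPX4 siRNA 60 replicates 1 or 3, scrambled 120 replicate 3 or GPX4 siRNA 120 replicate 1. Both were also lost with every probe on its own and with array weights, and the synthesis list with the strict filter and the replicate block. The highest adjusted p over all settings was 0.165 for oxidation and 0.301 for synthesis. Of 18 lipoprotein assembly genes DGAT1 and APOA1 fell and 0 rose (2 up and 4 down over the list alone, adjusted p = 0.744). That list's median of −0.01 and mean of 0.00160 differed in sign. None of 23 cholesterol synthesis genes passed (0 over the list alone, median −0.14, adjusted p = 0.13, but 0.0291 with the authors' series values). Of 12 eicosanoid genes, PLA2G2A, a secreted phospholipase, rose by 0.74 ± 0.18 (limma adjusted p = 0.0477, passing in 3 of the 12 fits, adjusted p up to 0.117; detected on 2 of 3 scrambled 60 arrays) and 0 fell (1 up and 4 down over the list alone, list adjusted p = 0.182).

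Among the selenoproteins, the family to which GPX4 belongs, GPX1 rose and GPX4 fell, and 16 of 18 measured did not pass (4 up and 3 down when adjusted over the list alone). The list as a whole did not pass (median 0.08, camera adjusted p = 0.537). SELENOK, a selenoprotein of the endoplasmic reticulum, was at 0.68 ± 0.17 (limma adjusted p = 0.0509, and 0.0457 without the array labelled scrambled 60 replicate 1). SELENOT was at 0.38 (0.237, and 0.02 without that array). SEPHS2, which makes the selenium donor for selenocysteine, was at −0.66 ± 0.20 (limma adjusted p = 0.0928). Thioredoxin reductases TXNRD1 and TXNRD2 were at 0.35 and −0.42, SELENOW at 0.44, MSRB1 at −0.25 and SELENOP at −0.34. Smaller log2 fold changes were found for SELENON (0.20), SELENOS (0.18), DIO1 (−0.18), SELENOO (0.14), SELENOI (−0.10), SELENOF (0.09) and GPX3 (0.07). GPX2, the gastrointestinal glutathione peroxidase, was at 0.01, and at −0.05 with median scaling and −0.04 with the authors' series values.

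Genes of the selenium insertion machinery (12 measured, median 0.05, camera adjusted p = 0.744), NRF2 targets and glutathione metabolism (30, 0.04, 0.749) and ferroptosis regulators (21, 0.02, 0.719) had no member past the threshold. Over the list alone the insertion machinery had 0 up and 1 down and the others 0. In these lists the endocytic receptor LRP2 was at −0.59, the glutathione transferase MGST2 at 0.78 and the mitochondrial iron-sulfur protein CISD1 at 0.55. None of 13 other antioxidant enzymes passed (0 up and 1 down over the list alone, adjusted p = 0.719), with catalase, CAT, at −0.48 and SOD2 at 0.50; the list's median of −0.02 and its test differed in sign. Iron and haem metabolism had 0 of 20 members past the threshold (0 up and 2 down over the list alone), with HEPH, an intestinal iron oxidase, at −0.52. Its median was −0.11 (camera adjusted p = 0.111), although fry, which asks whether a list's genes move one way without comparing them with other genes, gave 0.0117.

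Of the stress and growth lists only the proteasome passed as a whole. Of 21 genes of ATF4 and the integrated stress response, ATF3 rose, as did DDIT3, a transcription factor of that response, by 0.77 ± 0.19 (limma adjusted p = 0.0469, passing in 3 of the 12 fits with 1 array left out, adjusted p up to 0.110), and 0 fell (2 up over the list alone, list adjusted p = 0.275). BIK, a pro-apoptotic BH3-only gene, rose by 0.99 ± 0.20 (0.0167, and 0.0506 without GPX4 siRNA 60 replicate 1; detected on 2 of 3 scrambled 60 arrays) as the only one of 22 apoptosis regulators to pass (1 up and 1 down over the list alone, list adjusted p = 0.701). ENO2, a glycolytic enolase, rose by 0.52 ± 0.12 (0.0419, passing in 2 of the 12 fits, adjusted p up to 0.113) as the only one of 29 hypoxia and glycolysis genes (1 up and 1 down over the list alone, list adjusted p = 0.666). None of 16 p53 targets (list adjusted p = 0.604), 20 endoplasmic reticulum chaperones (0.767), 12 heat shock proteins (0.705), 32 DNA replication genes (0.871), 33 G2 and mitosis genes (0.265, but 0.0374 and lower with the authors' series values) or 33 translation initiation genes (0.749) passed, over the list alone or otherwise. Of 68 cytosolic ribosome genes RPL28 fell by 0.52 ± 0.11 (limma adjusted p = 0.0241, passing in 5 of the 12 fits, adjusted p up to 0.0804) and 0 rose (0 up and 1 down over the list alone). That list's median was 0.07 (adjusted p = 0.265, but 0.0248 with median scaling). For 31 proteasome genes none passed (0 over the list alone), with PSMD1 at 0.30 and a median of 0.11. The proteasome's camera adjusted p was 0.0406, and its adjusted p = 0.46 with an estimated correlation. That call was lost under 11 of 22 other settings, among them median scaling, the authors' series values, the replicate block, array weights, and leaving out the array labelled scrambled 60 replicate 1, GPX4 siRNA 60 replicates 1 or 3, scrambled 120 replicates 1 or 3, or GPX4 siRNA 120 replicate 2, with adjusted p up to 0.187.

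The list of metallothioneins, which bind zinc and copper, was higher as a group by the preset-correlation test (median 0.24, camera adjusted p = 0.0222), but not with an estimated correlation (adjusted p = 0.46). Its fixed members also include MTF1 and SLC30A1, which are not metallothioneins. MT2A rose by 0.68 ± 0.14 (limma adjusted p = 0.02, passing in 7 of the 12 fits with 1 array left out, adjusted p up to 0.0603; detected on only 1 of 3 scrambled arrays at each dose). MT1X was at 1.04 and MT1A at 0.73, and 6 of 7 members did not pass (3 up and 0 down over the list alone). Goblet and secretory cell markers were mixed. LYZ, lysozyme, rose by 0.71 ± 0.13 (0.0112) on its brightest probe and was at −0.23 on its other probe. REG3A, an antimicrobial lectin, rose (0.00943), with no size given since it was not well above background on any scrambled 60 array and on 1 of 3 scrambled 120 arrays only. AGR2, a disulfide isomerase of mucin-secreting cells, fell (0.0477, passing in 2 of the 12 fits, adjusted p up to 0.126), with no size given since it was detected on 2 of 3 GPX4 siRNA 60 arrays and on 0 of 3 GPX4 siRNA 120 arrays. The other 7 of 10 did not pass (4 up and 1 down over the list alone), and the median was 0.27 (camera adjusted p = 0.0406, and adjusted p = 0.356 with an estimated correlation). The metallothionein and goblet calls were lost without the array labelled scrambled 60 replicate 1 or scrambled 120 replicate 2, and the goblet call also without GPX4 siRNA 60 replicate 3 or GPX4 siRNA 120 replicate 3, with adjusted p up to 0.301 and 0.279 over all settings. Both calls were also lost with no filter and with array weights, and the goblet call with no background correction (adjusted p = 0.0823), with every probe on its own and with the replicate block.

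The remaining lists gave no call in the reported fit. None of 25 tight junction and adhesion genes passed (0 up and 2 down over the list alone, median −0.12, camera adjusted p = 0.0873, fry 0.0456, but camera adjusted p = 0.0443 with no background correction and 0.026 with the authors' series values), with E-cadherin, CDH1, at −0.55. Of 13 mesenchymal genes TAGLN, an actin-binding protein, rose by 0.57 ± 0.12 (limma adjusted p = 0.0227, passing in 6 of the 12 fits, adjusted p up to 0.0740). FN1, fibronectin, fell by 0.68 ± 0.17 (0.0433) on its brightest probe, detected on 1 and 2 of 3 GPX4 siRNA arrays at 60 and 120 pmol, passed in 1 of the 12 fits (adjusted p up to 0.992) and was at −0.05 on its other probe (1 up and 2 down over the list alone, list adjusted p = 0.744). Interferon-stimulated genes (24 measured, list adjusted p = 0.666), NF-kappaB and cytokine targets (10, 0.147), RNA interference machinery (12, 0.666) and reference genes (16, 0.426) had no member past the threshold. Over the list alone the interferon list had 1 up and 1 down, RNA interference 1 up, and the others 0. ISG15 was at 0.74, CCL2 at 0.43, TNRC6A at 0.52 on its brightest probe (−0.30 on its other probe) and GUSB at −0.32. Among fibroblast markers, COL3A1 rose and PDGFRB, a growth factor receptor, fell by 0.57 ± 0.13 (0.0352, passing in 2 of the 12 fits, adjusted p up to 0.1) among 5 measured (1 up and 2 down over the list alone). The fibroblast list did not pass (adjusted p = 0.705, median −0.26 and mean 0.04), and COL1A1 was at −0.29. Of 7 leukocyte markers LYZ rose and 6 did not pass (2 up and 1 down over the list alone, list adjusted p = 0.744), with CD14 at −0.51. Only 4 of 11 endothelial markers were measured, too few for a test. Medians lay below 0 while the test pointed up for the replication, translation initiation, chaperone, hypoxia, interferon and leukocyte lists. In all, 11 of 42 lists passed, 8 higher and 3 lower; 4 passed without the array labelled scrambled 60 replicate 1 and 7 without scrambled 120 replicate 2.

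At 60 pmol alone, IGFBP1 was at least 4.12-fold higher with GPX4 siRNA (limma adjusted p = 3.45e-05). PAGE4 rose by 2.25 ± 0.26, NKD1 by 1.69 ± 0.15, RN7SK by 1.58 ± 0.24 and COL3A1 by 1.56 ± 0.18, with limma adjusted p from 3.45e-05 to 0.00541. EVL fell by 1.84 ± 0.18 (9.72e-05), FGA by 1.44 ± 0.22 (0.00608, but 0.0514 without GPX4 siRNA 60 replicate 2 and 0.0643 with only the 6 arrays of the comparison) and STOM by 1.43 ± 0.20 (0.00316, and 0.0624 with only those arrays). LOXL4, a lysyl oxidase-like enzyme, fell by 1.16 ± 0.19 (0.0128; detected on 2 of 3 GPX4 siRNA 60 arrays), passing in 8 of the 12 fits with 1 array left out (adjusted p up to 0.0986). The unnamed transcript HS.50125 fell by 1.19 ± 0.20 (0.0149), passing in 7 of them (adjusted p up to 0.105). Altogether 35 genes changed, 21 up and 14 down, with 1795 at an unadjusted p under 0.05 and 709 expected by chance. The split was 14 up and 21 down with median scaling, 30 and 41 with no background correction, and 25 and 120 with the authors' series values. With only the 6 arrays of the comparison it was 8 up and 1 down, so at most 1 of the falls named here passed there. The count was 21 without scrambled 60 replicate 2, 69 without scrambled 60 replicate 3, and 17, 14 and 17 without GPX4 siRNA replicates 1, 2 and 3. Treated and control arrays did not overlap for 2642 genes (18.6%), against 10% by chance. Of the lists, 15 passed, 11 higher and 4 lower, and 3 did without the array labelled scrambled 60 replicate 1. The Wnt list (3 up, 0 down, median 0.33, adjusted p = 1.26e-05) was the only one to hold with an estimated correlation, at adjusted p = 0.0456.

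At 120 pmol alone, PAGE4 rose by 1.96 ± 0.26, NKD1 by 1.57 ± 0.15, COL3A1 by 1.5 ± 0.18 and MYBPH by 1.49 ± 0.18, with limma adjusted p from 7.45e-05 to 0.00164, and IGFBP1 was at least 3.16-fold higher (0.000535). The probe of KRT18, a keratin of simple epithelia, fell by 2.66 ± 0.21 (9.73e-06), that of RPL21, a ribosomal protein gene, by 2.35 ± 0.25 (0.000206), and LOC654194, a gene model without a current symbol, fell by 2.74 ± 0.36 (0.00164). The other KRT18 probe was at 0.45, but it lay near background on all arrays (signals 113 to 190). EVL fell by 1.76 ± 0.18 (0.000173) and SLC10A1 by 1.58 ± 0.23 (0.00419, and 0.0578 with the authors' series values). In all 39 genes changed, 14 up and 25 down, with 1533 at an unadjusted p under 0.05. The count was 88 without the array labelled scrambled 60 replicate 1, which enters only through the shared estimate of spread, normalization and filter. It was 18, 20 and 19 without scrambled 120 replicates 1, 2 and 3, and 20 and 17 without GPX4 siRNA 120 replicates 2 and 3. Treated and control arrays did not overlap for 2617 genes (18.5%, against 10% by chance). The Wnt list was the only one to pass (2 up, 0 down, median 0.38, adjusted p = 9.26e-08), and its adjusted p = 0.0127 with an estimated correlation.

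**Figure D4:**
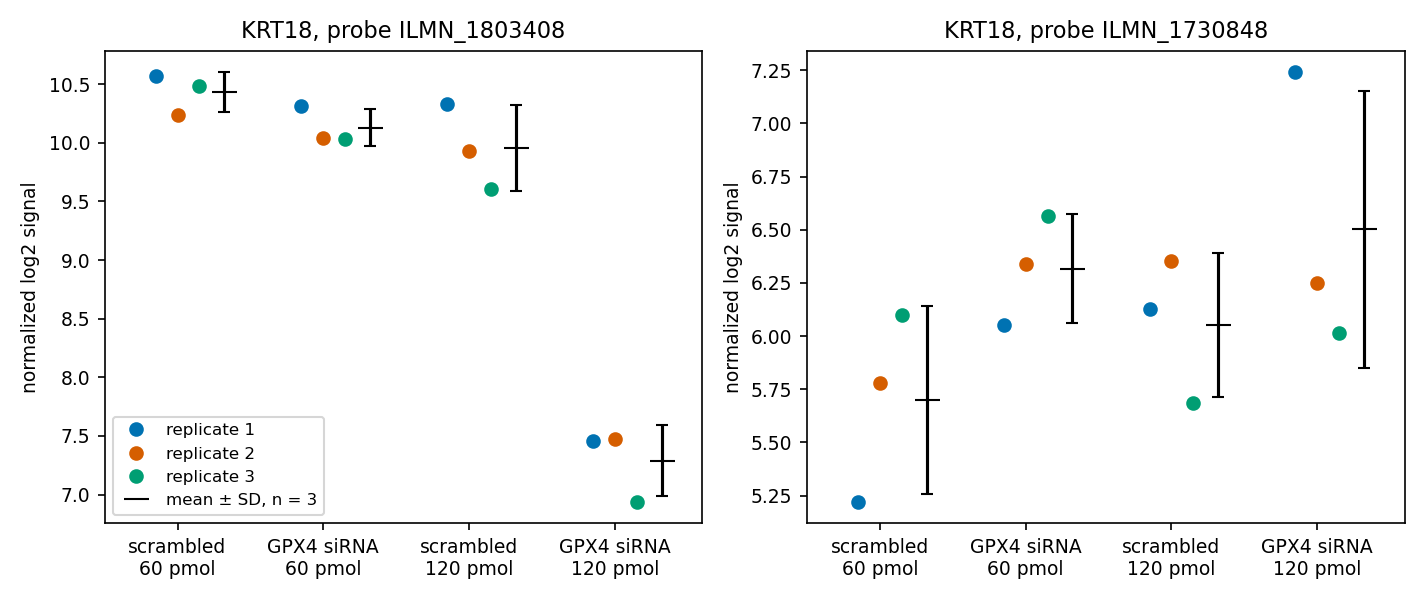
Normalized log2 signal of both KRT18 probes on each array, by group, with bars at the mean ± SD of 3 arrays. With 120 pmol GPX4 siRNA, ILMN_1803408 lies between 6.94 and 7.47, against 9.60 to 10.57 on the other 9 arrays, and ILMN_1730848 lies between 6.02 and 7.24.

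Both doses moved genes alike in part. The log2 fold changes at 60 and at 120 pmol, which share no array, correlated across genes with Pearson's r = 0.386 and Spearman's rho = 0.324; genes are not independent replicates. Of the genes called at each dose, 18 were called at both, all in the same direction, where independent lists would share 0.0454 in the same direction. The 2 lists of calls share one estimate of spread per gene, and genes vary together, so that number may be too low. Of the 35 called at 60 pmol 34 had the same sign at 120 pmol, and of the 39 called at 120 pmol 37 had the same sign at 60 pmol. The effect of GPX4 siRNA differed between doses for 2 genes by limma, with 709 at an unadjusted p under 0.05, as many as chance gives. KRT18 was lower at 120 than at 60 pmol by −2.36 ± 0.29 (limma adjusted p = 0.00653, and 0.0644 without the array labelled scrambled 60 replicate 1 and scrambled 120 replicate 2 together). RPL21 was lower by −2.66 ± 0.35 (0.00773, but 0.224 with the authors' series values and 0.0827 with no filter on dim probes). The effect also differed for 6 lists, all lower at 120 pmol: complex I, the mitochondrial and cytosolic ribosome, the proteasome, other antioxidant enzymes and goblet markers. None of the 6 held with an estimated correlation (adjusted p from 0.683 to 0.853), and none passed without the array labelled scrambled 60 replicate 1.

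Between the doses of scrambled siRNA no gene changed by limma, with 649 at an unadjusted p under 0.05 and 709 expected by chance. With median scaling 2241 genes had such a p and with the authors' series values 1873, and again 0 passed after adjustment. By camera 7 lists were higher at 120 pmol. They were complexes I, IV and V (medians 0.21, 0.23 and 0.25), both ribosome lists, NRF2 targets (0.14) and other antioxidant enzymes (0.28), and none held with an estimated correlation (adjusted p from 0.326 to 0.893). Complex I genes lay 0.86 below their average on the array labelled scrambled 60 replicate 1. Between the doses of GPX4 siRNA 8 genes changed. LOC654194 fell by 3.54 ± 0.36 (limma adjusted p = 0.000163), KRT18 fell by 2.84 ± 0.21 (3.86e-06) and RPL21 by 2.83 ± 0.25 (3.02e-05). LOC644889 fell by 2.32 ± 0.39 and LOC440055 by 1.83 ± 0.32 (both 0.0499), each passing in 4 of the 12 fits with 1 array left out (adjusted p up to 0.317 and 0.321), and LOC644889 was detected on 2 of 3 GPX4 siRNA 120 arrays. LOC647436 rose by 1.08 ± 0.17 (0.0235), passing in 6 of them (adjusted p up to 0.251). The remaining genes, RPL26 at −1.68 (0.0409, 4 of 12, up to 0.264) and HNRNPA1 at −0.89 (0.0499, 1 of 12, up to 0.358), are named after their values were seen. The count of 8 became 3 on leaving out any GPX4 siRNA array, 4 without scrambled 60 replicate 2 and 5 without scrambled 120 replicate 3. Goblet and secretory cell markers were the only list to pass (median −0.22, camera adjusted p = 0.006), with adjusted p = 0.173 with an estimated correlation.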

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

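The tests of a wrong label, of outlying arrays, of single probes, and of GPX4 depletion for the lost probes were chosen after the result was seen, as were leaving out 2 arrays together and, for the difference between doses, the splits by dose within each siRNA. The effect of GPX4 siRNA differed between doses for KRT18 (−2.36, limma adjusted p = 0.00653) and RPL21 (−2.66, 0.00773). It also differed for 6 gene lists by camera with the preset correlation, but for none of them with an estimated correlation (adjusted p from 0.683 to 0.853). Their medians of the effect at 120 minus that at 60 pmol were −0.30 for complex I (adjusted p = 0.00456) and −0.245 for the mitochondrial ribosome (0.00047). They were −0.39 for other antioxidant enzymes (0.0425), −0.154 for the cytosolic ribosome (0.0394), −0.141 for the proteasome (0.0382) and −0.179 for goblet and secretory cell markers (0.0387). None of these 6 lists passed without the array labelled scrambled 60 replicate 1. Groups of 3 arrays are too small for a test of single outlying values.

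The first pattern is the GPX4 signal of the array labelled scrambled 60 replicate 1, at the level of the GPX4 siRNA arrays. A GPX4 siRNA sample under a scrambled label is argued against: over 87 genes changed at 120 pmol, this array lay at −0.0507 on a scale from the other scrambled 60 arrays (0) to the GPX4 siRNA 60 arrays (1). Loss of part of the abundant transcripts in this array stays open as a candidate explanation. Of the 500 genes nearest to GPX4 in level, 18.4% lay at least as far below the other scrambled 60 arrays as GPX4 did, against 0 to 2.6% in the other scrambled arrays. Genes as far above and genes of other levels were not counted. This array deviated from the others at large (median correlation 0.964), so the share does not single out a loss of abundant transcripts.

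The second pattern is the higher level of complex I, IV and V and mitochondrial ribosome genes with GPX4 siRNA, a median of 0.26 over 128 genes, with all 4 lists called by the preset correlation and none with an estimated correlation (adjusted p from 0.462 to 0.632). Without the array labelled scrambled 60 replicate 1 the median was 0.143 (0.127 at 60 pmol and 0.156 at 120 pmol), and 2 of the 4 lists passed. Without scrambled 120 replicate 2 as well it was 0.0919 and 0 of the 4 lists passed, with 0.0323 at 120 pmol (−0.00351 to 0.0448 on leaving out 1 more array). At 60 pmol it was then 0.126 (0.0432 to 0.187), and complex IV and the mitochondrial ribosome passed (both adjusted p = 0.023, but 0.484 and 0.36 with an estimated correlation). These were the scrambled arrays lowest in the 128 genes at their dose, so leaving them out was bound to shrink the difference, and outlying scrambled arrays and depletion of GPX4 at both doses cannot be told apart.

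The third pattern is the loss of signal of 9 probes, those of KRT18 and RPL21 among them, with 120 pmol GPX4 siRNA relative to 60 pmol. For the 4 of these probes whose gene had another probe detected on all arrays, the median was −2.59, against 0.0502 for the other probes, so signal lost by single probes is a candidate explanation. The other KRT18 probe lay near background (signals 113 to 190), as did 1 of the 2 other ADK probes (131 to 217). These could show little of a fall. The other probes of CLEC2D and RPL10A, bright on all arrays, were at −0.0107 and −0.0269. The median of the 9 probes was 0.279 at 60 pmol, against −1.58 at 120 pmol. They were selected as lower at 120 than at 60 pmol, so these medians decide nothing about depletion of GPX4. The effect differed between doses for the probes of CLEC2D, LOC654194, KRT18 and RPL21 (limma adjusted p over all probes from 0.0042 to 0.0456), but not for the others (0.491 or 0.912). GPX4 mRNA left on ILMN_2378952 was 56.6% at 60 and 52.5% at 120 pmol, without a detectable difference (0.968). Those falls thus did not follow the measured GPX4 mRNA, but the probes are the top of a selected set, so depletion of GPX4 stays open. In scrambled 120 replicates 1, 2 and 3 the medians relative to scrambled 60 were 0.275, −0.772 and −0.56, so part of the loss was also seen without GPX4 siRNA. The scrambled 60 mean includes replicate 1, itself low for some of these probes. In scrambled 60 replicates 1, 2 and 3 the RPL10A probe was at 11.75, 12.6 and 12.73 (normalized log2) and the KRT18 probe at 10.57, 10.24 and 10.48. Isoforms that carry only the lost probes were not tested.

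Other splits of the arrays were counted for each comparison. For the mean of both doses, 1 of 100 splits within doses, the real one, gave as many genes as the real split. The count was 282, with 4 as the highest of the others. Those others mix GPX4 and scrambled siRNA arrays, which carries any siRNA effect into their spread and lowers their counts. Only 100 of the 200 possible splits were drawn. A share of 1 of 100 thus argues against chance but does not exclude it. For the correlation between doses the share was also 1 of 100, but the highest other, 0.352, lay close to the real 0.386. Chance is not excluded there either. For the number of lists the share was 5 of 100 (11 against a highest other of 13, with a median of 4). For the number of genes whose effect differs between doses it was 13 of 100 (2 against a highest other of 9). Neither share was under 0.05, so chance stays open for both. The latter splits exchanged doses within each siRNA, since splits that mix GPX4 and scrambled siRNA arrays carry the siRNA effect into the spread. For a single dose and between doses of one siRNA, 10 splits are too few for a share under 0.05. There the real and the highest other count were 35 and 0 at 60 pmol (1 of 10), 39 and 0 at 120 pmol (1 of 10), 0 and 2 between scrambled doses (10 of 10), and 8 and 0 between GPX4 siRNA doses (1 of 10).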

How the results depend on the processing

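Leaving out the array labelled scrambled 60 replicate 1 and scrambled 120 replicate 2 together was chosen after seeing the data; all other alternatives were planned. GPX4 fell in every alternative tried, by 0.79 to 1.08. The Wnt and brush border lists passed in all of them with the preset correlation, and of these the Wnt list alone with an estimated correlation (adjusted p = 0.0117, against adjusted p = 0.181). Of the 282 genes, 253 were called in the same direction without the array labelled scrambled 60 replicate 1 and 207 without both arrays. Of 87 called values of named genes, 77 kept their call with median scaling and 75 with the authors' series values. Without a filter, where more genes are tested, 73 of the 87 kept it, and of the 67 that pass the strict filter 66 did. IGFBP1, with no scrambled array above background, has only a bound. Numbers of genes for the mean of both doses were 494 with no background correction, 510 with the series values and 1339 with array weights. At 60 pmol they were 71, 145 and 1136 with these, 59 with the strict filter, 60 with a trended robust variance and 9 with only the arrays of the comparison, where fewer arrays estimate the spread. At 120 pmol they were 110 with array weights and 65 without the 2 arrays. For the difference between doses they were 1 with the series values, 4 with every probe on its own, 4 with array weights and 1 without the 2 arrays. Between GPX4 siRNA doses they were 5 with no background correction, 4 with the series values, 5 with no filter, 16 with array weights and 3 with the replicate block. Between scrambled doses limma gave 0 in every alternative (649 at an unadjusted p under 0.05 in the reported fit, but 2241 with median scaling, 1873 with the series values and 1880 with array weights, where chance gives 709). Numbers of lists were 3 with array weights, 2 without the 2 arrays, 1 with an estimated correlation and 6 with fry. The correlation between doses was 0.466 with no background correction, 0.459 with the series values, 0.297 with no filter and 0.476 with the strict filter. The causes of these differences, that of the 9 genes at 60 pmol included, were not tested. With only the arrays of the comparison, 120 pmol gave 37 genes against 39 in the reported fit.

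Leaving out 1 array gave 147 to 504 genes for the mean of both doses, 14 to 69 at 60 pmol, 17 to 88 at 120 pmol, 2 to 3 for the difference between doses, 3 to 9 between GPX4 siRNA doses, 4 to 14 lists, a correlation of 0.256 to 0.435 (the lowest without scrambled 120 replicate 2, 0.332 without scrambled 60 replicate 2 and 0.336 without GPX4 siRNA 120 replicate 1) and a GPX4 change of −1.04 to −0.79. GPX2, near 0 and not called, was at −0.0484 with median scaling, −0.0434 with the series values, −0.059 with array weights, −0.20 without the 2 arrays and between −0.11 and 0.0992 on leaving out 1 array. SELENOI, not called either, was at 0.0465 with array weights and between −0.17 and 0.0233 on leaving out 1 array. SLC23A1 ranged from −1.21 to 0.0097, and FN1 from −0.73 to 0.0724, with 0.0057 without GPX4 siRNA 60 replicate 2 and its highest value without GPX4 siRNA 120 replicate 1, since another probe of the gene was then the brightest. Replicate numbers are shared between groups, but of 18 same-number pairs 1 had deviations correlated above 0.1 (−0.314 to 0.101). Between the siRNAs of the same dose these were 0.0754, 0.0663 and 0.0209 at 60 pmol, and 0.0439, 0.101 and −9.3e-05 at 120 pmol. With 3 arrays per group, pairing by replicate number is neither shown nor excluded. With the replicate number as a block the counts were 226 for the mean of both doses, 24 at 60 pmol, 32 at 120 pmol, 2 for the difference, 3 between GPX4 siRNA doses, and 8 lists. A slide block was not run, as the files name no slide.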

Other observations

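The lists of plasma protein, immediate early and BMP genes were written after the named genes had been seen, with their predictions before each test, and the genes named here were chosen after their values were seen. Genes of liver-type plasma proteins were lower with GPX4 siRNA as a group, in a cell line of intestinal origin. Besides the fibrinogen chains, KNG1, the kininogen precursor of bradykinin, fell by 0.91 ± 0.12 (limma adjusted p = 0.000619) and AFP, alpha-fetoprotein, by 0.93 ± 0.16 (0.00638). ALB, serum albumin, fell by 0.90 ± 0.13 (0.00183), and SERPINC1, antithrombin, by 0.68 ± 0.12 (0.00755). Of 35 measured of 55, 33 lay below 0, 7 fell and 0 rose, with a median of −0.29. The hypothesis that such genes fell together passed its test by limma's camera (adjusted p = 2.36e-12 over these 3 lists, 7.86e-13 unadjusted, and adjusted p = 1e-04 with an estimated correlation). It also passed at 60 pmol (median −0.25, limma's camera adjusted p = 5.76e-05, and 0.00336 with an estimated correlation). At 120 pmol the median was −0.39 (adjusted p = 2.3e-15, and 4.23e-05 with an estimated correlation). Without the array labelled scrambled 60 replicate 1 the median was −0.34 (limma's camera adjusted p = 9.78e-16). The fibrinogen genes, which prompted this list, and the apolipoproteins were left out of it. The same arrays both prompted and tested the list, so its p-values are no independent support, at either dose or for their mean.

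A further hypothesis, that JUN and ATF3 rose with immediate early and AP-1 genes at large, did not pass (limma's camera adjusted p = 0.134, and 0.134 unadjusted). Of 27 measured genes 2 rose and 0 fell: PHLDA1, an immediate early gene, by 0.90 (limma adjusted p = 0.000798) and EGR1, a zinc finger transcription factor, by 0.71 (0.0248, passing in 7 of the 12 fits with 1 array left out). The median of −0.05 and the test, which pointed up, differed in sign. That ID3 rose with BMP and TGF-beta response genes did not pass either for the mean of both doses (limma's camera adjusted p = 0.127, 0.0845 unadjusted), although fry gave an adjusted p of 0.0219. At 60 pmol alone the list passed (median 0.20, limma's camera adjusted p = 0.0183, and adjusted p = 0.0453 with an estimated correlation). With an estimated correlation that call was lost without the array labelled scrambled 60 replicate 1 (adjusted p = 0.0732) and without scrambled 120 replicate 2 as well (adjusted p = 0.0921), where the preset correlation gave 0.0348 and 0.0429. At 120 pmol it did not pass (median −0.05, limma's camera adjusted p = 0.618), and the difference between doses was not tested for this list. Of 11 measured, BAMBI, a decoy receptor of the family, rose by 0.86 (limma adjusted p = 0.00707) and ID1 by 0.83 (0.0208, passing in 6 of the 12 fits), with a median of −0.01 against a test pointing up.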
